A study of Homo sapiens with 6 samples.

How the data were processed

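RNA sequencing was performed on total RNA extracted with TRIzol from 6 samples of A431 cells, 3 with a control shRNA and 3 with an shRNA against ARID1A, as the sample titles name them. Libraries followed Illumina's standard procedures, per the labels' protocols. The strandedness of the libraries, the number of different shRNAs and the genome build are not given in the sources used here, so no coordinates are printed and overlapping or antisense genes cannot be told apart. HISAT2 2.0.5, an aligner, and featureCounts 1.5.0-p1, a read counter, are listed per the submitters' processing notes, with no settings.

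The authors deposited 1 table of FPKM values, with 1 column per sample and a column of gene lengths. FPKM is the number of fragments or reads assigned to a gene per kilobase of its length, scaled to the reads assigned in the sample. The table has 26048 rows, of which 6234 are empty and 19814 name a gene. Over the first 19421 rows, value times length summed to 1000000000 in every sample, and 100% of the values were whole multiples of what 1 read is worth (tolerance 0.01 reads). The number of assigned reads per sample, 31658040 to 36453744, was recovered from this step. The last 393 rows have another denominator, which implies 34693342 to 36908848 reads, and 363 of them name genes listed before with other values. These 393 rows, 386 of them on the X chromosome, were left out of all tests. The remaining 19421 gene IDs are NCBI gene IDs, of which 19344 matched the RefSeq names of GRCh38.p14, used for names and gene types only. No mitochondrial genes are among the rows analysed, and 448 genes were at 0 in all samples. Members of the fixed lists not analysed here include PROM1, THY1, LORICRIN, LCE3D, TWIST2, CDH11, CCL2, S100A7, S100A8, HLA-DRA, H3C4 and the 13 mitochondrially encoded genes.

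FPKM values are not counts, so the test was limma 3.58.1 (R 4.3.3; lmFit and eBayes with a mean-variance trend) on log2(FPKM + 1), that is with a pseudocount of 1 FPKM, without covariates, two-sided, for the 11599 genes with a mean of at least 1 FPKM over all 6 samples, 10777 of them protein-coding. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 2-fold minimum is a log2 fold change of at least 1. A count test had been planned only for a table of raw counts, and the recovered reads were tested with limma voom alone, as an alternative. An exact permutation test of the 6 ARID1A values was added. With 3 samples per group the fit has 4 residual degrees of freedom before limma shares the spread across genes. The table's tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

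There were 21 gene lists fixed before the data were examined, 4 of them checks of cell type and RNA make-up, and 18 had at least 5 tested members. Counts given for a list cover its tested members only. They were tested with limma's camera, which compares a list with the other genes, at a preset correlation of 0.01 with adjustment over the 18 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in one direction without comparing them with other genes, were alternatives. Of the 18 lists, 8 passed with the preset correlation, 2 with an estimated correlation and 15 with fry. The genes named were chosen by a rule fixed before the data were examined. They are ARID1A, ARID1B, RB1, E2F1 and MYC, the 6 protein-coding genes with the largest increase and the 6 with the largest decrease among those past the threshold whose groups do not overlap, and the 3 members of each list (checks excepted) with the smallest p. This gave 65 genes, and some results are not reported here.

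Replicates of a group were compared before averaging. The chi-square per degree of freedom between the recovered reads of 2 samples of a group lay between 5.56 and 90.5, so no pair differed as little as counting noise. Samples with the same replicate number deviated together from their group means, with correlations across genes of 0.321, 0.187 and 0.315 for numbers 1, 2 and 3, all over 0.1, while pairs with different numbers lay between -0.302 and 0.0859. Deviations from a group mean sum to 0, so values above 0 for equal numbers push those for different numbers below 0. The 2 sides of this contrast are thus not separate evidence, and 3 samples per group allow too few matchings to exclude chance. By this check, which comes from the data and not from the labels, the numbers may pair the samples. A fit with the replicate number as a block was an alternative. On principal components of the tested genes, the first component (55.4% of the variance) separated the groups and the second (25.0%) set shARID1A replicate 3 apart.

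The alternatives fixed before the data were examined were pseudocounts of 0.1 and 5 FPKM, no filter, a minimum of 5 FPKM, rescaling to an equal FPKM sum per sample (the TPM scale), upper quartile scaling, quantile normalization, no mean-variance trend, robust eBayes, the replicate block, and leaving out each sample. After the data were seen, limma voom on the recovered reads, cyclic loess normalization with the replicate block, and a per-sample correction for gene length and GC content with the replicate block were added. GC content was known for 98.9% of the genes tested and was fitted with splines of 5 degrees of freedom. It came from GENCODE transcripts, for each gene the one nearest to the gene length in the deposited data. The procedure was tested on simulated data drawn from the real means and library sizes for this comparison. Among 11600 genes, 200 were changed 2-fold or 1.5-fold, and the members of 1 further list were raised by a smaller fold. The procedure recovered 97% of those changed 2-fold and 54% of those changed 1.5-fold, and 6.32% of its calls were unchanged genes. With no change simulated it made 0 calls, and 0 of 21 unchanged lists passed camera. The simulated genes varied independently of one another, with a spread set by expression level alone and without a replicate effect, and the unchanged lists were drawn at random. The simulation therefore does not show how often camera passes lists whose members vary together, as in real data.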

Results

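Gene expression was measured by RNA sequencing in A431, a human squamous carcinoma cell line that carries many extra copies of the EGFR gene, grown in DMEM with 10% FBS. There were 6 samples in 2 groups. In 3 samples the cells expressed a control shRNA (shCONTROL) and in 3 they expressed an shRNA against ARID1A (shARID1A), the DNA-binding subunit of the BAF form of the SWI/SNF chromatin remodelling complex. The reads assigned to genes, recovered from the deposited FPKM values, numbered 31658040, 34547753 and 34647924 in the shCONTROL samples and 36453744, 32561039 and 34634097 in the shARID1A samples. Of 19421 genes with one common scale, 11599 had a mean of at least 1 FPKM over the 6 samples and were tested. The labels do not say whether the 3 samples of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical. All fold changes are differences of group means of log2(FPKM + 1), which understates the change of genes with low FPKM, and adjusted p-values come from limma with Benjamini-Hochberg adjustment over all genes tested unless stated otherwise.

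The comparison asks which genes change when ARID1A is knocked down, and the study is known to be concerned with pRb, E2F1, c-Myc and stem-like properties in squamous carcinoma. The targeted gene came first. ARID1A (gene ID 8289) stood at 22.8, 22.8 and 23.8 FPKM in the shCONTROL samples and at 6.70, 7.62 and 7.31 FPKM in the shARID1A samples. The mean fell from 23.1 ± 0.60 to 7.21 ± 0.46 FPKM (SD, n = 3 per group), which is 68.8% lower, and each sample matched its label. At least 2098 reads lay behind each value. The log2 fold change was -1.55 with a standard error of 0.094 (limma, adjusted p = 0.000187). An exact two-sided permutation test gave p = 0.1, the smallest value that 3 samples against 3 allow.

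The paralog of ARID1A and the 3 other genes named by the study's question did not pass the test. ARID1B (gene ID 57492), the alternative DNA-binding subunit of the same complex, stood at 9.36 ± 0.16 FPKM with the control shRNA and 9.03 ± 0.47 FPKM with the ARID1A shRNA (limma, adjusted p = 0.758). The sign of this small difference turned after quantile normalization and after cyclic loess normalization with the replicate block. RB1 (gene ID 5925), which encodes pRb, the inhibitor of E2F factors, stood at 17.5 ± 2.79 and 16.5 ± 5.44 FPKM (adjusted p = 0.745), and its sign turned without shCONTROL replicate 3 (log2 fold change 0.010) or shARID1A replicate 2 (0.082). MYC (gene ID 4609) stood at 132 ± 30.3 and 120 ± 28.7 FPKM (adjusted p = 0.683), and its sign turned without shARID1A replicate 3 (0.053). E2F1 (gene ID 1869) stood at 6.83 ± 0.30 and 10.2 ± 2.45 FPKM, a log2 fold change of 0.50 with an adjusted p of 0.0617. With the replicate number as a block the adjusted p of E2F1 was 0.0264, and without shARID1A replicate 3 it was 0.00941. E2F1 also passed after quantile normalization, and with the block after cyclic loess or after length and GC correction. In the other settings that keep all samples it missed the threshold. Over all alternatives its adjusted p ranged from 0.00941 to 0.178.

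**Figure D1:**
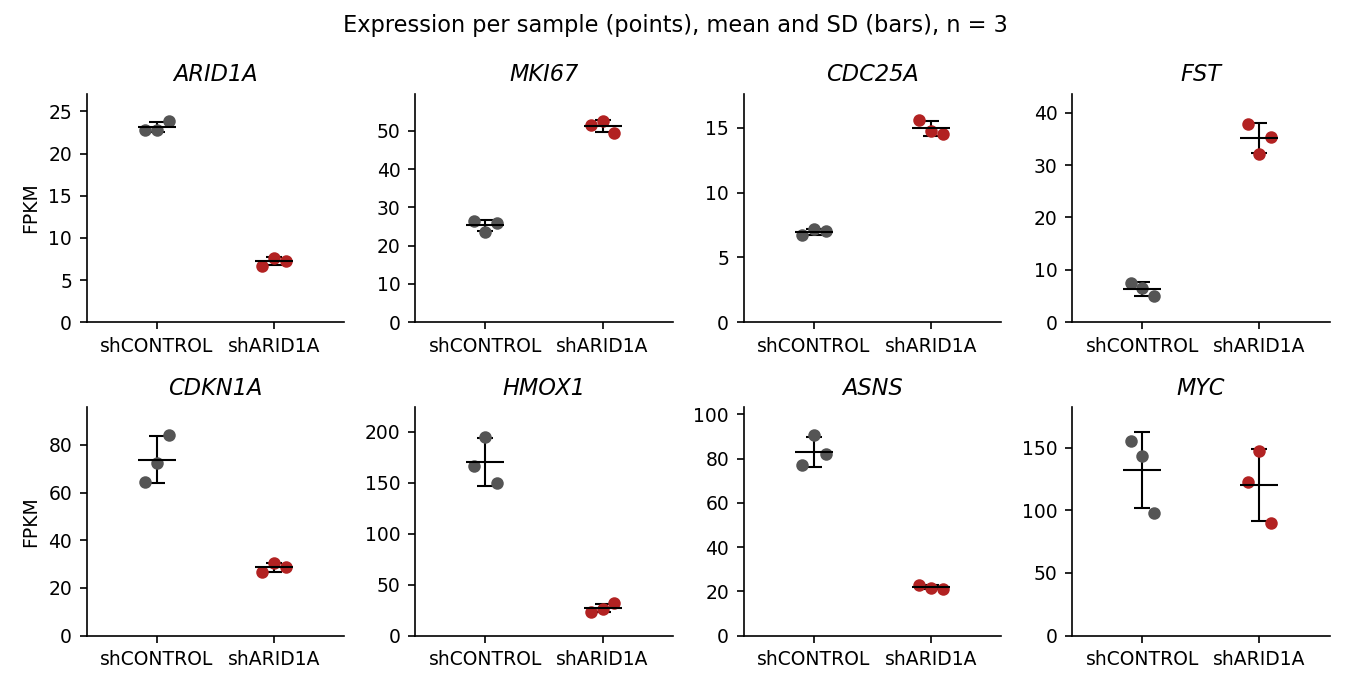
FPKM (vertical axes) of 8 genes in the 3 shCONTROL samples (grey points) and the 3 shARID1A samples (red points); horizontal bars are group means and whiskers are SD, n = 3. The groups do not overlap for ARID1A (7.21 against 23.1 FPKM on average), MKI67, CDC25A, FST, CDKN1A, HMOX1 and ASNS, and they overlap for MYC.

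Across the transcriptome, 1944 of the 11599 genes tested (16.8%) changed, 679 of them higher and 1265 lower with the ARID1A shRNA (limma, adjusted p below 0.05). The median log2 fold change over all genes tested was -0.08. The counts and medians of the gene lists below are to be read against that share and that median. At least 2-fold changes were seen in 209 genes, 53 higher and 156 lower, against 86 and 116 after quantile normalization and 85 and 124 after cyclic loess normalization with the replicate block. Their number was 68 with a pseudocount of 5 FPKM, 136 with a minimum of 5 FPKM, 363 with a pseudocount of 0.1 FPKM and 392 with voom. Among protein-coding genes whose 3 values per group did not overlap, FST and TGM2 had the largest increases and HMOX1 and LCN2 the largest decreases. FST (gene ID 10468), the activin antagonist follistatin, rose from 6.31 ± 1.28 to 35.2 ± 2.86 FPKM, and TGM2 (gene ID 7052), a protein-crosslinking transglutaminase, from 14.6 ± 4.79 to 69.3 ± 6.60 FPKM. The chemokine CXCL1 (gene ID 2919), the pentraxin PTX3 (gene ID 5806), STEAP1 (gene ID 26872) and the metalloprotease ADAM19 (gene ID 8728) had log2 fold changes of 2.02, 1.73, 1.68 and 1.66. HMOX1 (gene ID 3162), heme oxygenase 1, fell from 170 ± 23.2 to 27.3 ± 4.05 FPKM (log2 fold change -2.60, limma adjusted p = 0.000116), and AKR1C1 (gene ID 1645), an aldo-keto reductase, from 408 ± 55.1 to 89.9 ± 17.4 FPKM (-2.18). LCN2 (gene ID 3934), a siderophore-binding protein, the leukotriene hydroxylase CYP4F3 (gene ID 4051), the glutathione-degrading enzyme CHAC1 (gene ID 79094) and the stress-responsive NDRG1 (gene ID 10397) had log2 fold changes of -2.34, -2.28, -2.01 and -2.01. All 12 of these genes had an adjusted p of at most 0.00169 and kept their calls in every alternative. AKR1C1 and CYP4F3 have close paralogs with which reads may be shared, so their exact levels are uncertain.

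The predominance of lower genes among the calls depended on the normalization. It stayed when each sample was rescaled by 1 factor, but not after quantile or cyclic loess normalization. Of the calls, 34.9% were higher with FPKM as deposited. The share was 36.6% with an equal FPKM sum per sample (659 higher, 1142 lower) and 41.5% after upper quartile scaling (771 higher, 1088 lower). It was 53.3% after quantile normalization (947 higher, 831 lower) and 52.3% after cyclic loess normalization with the replicate block (1251 higher, 1139 lower). Without shCONTROL replicate 1, shCONTROL replicate 2 or shARID1A replicate 1 the number of changed genes fell to 748, 587 and 786, and without shARID1A replicate 3 it was 3403. No gene called among the 1944 had the opposite sign in any alternative.

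**Figure D2:**
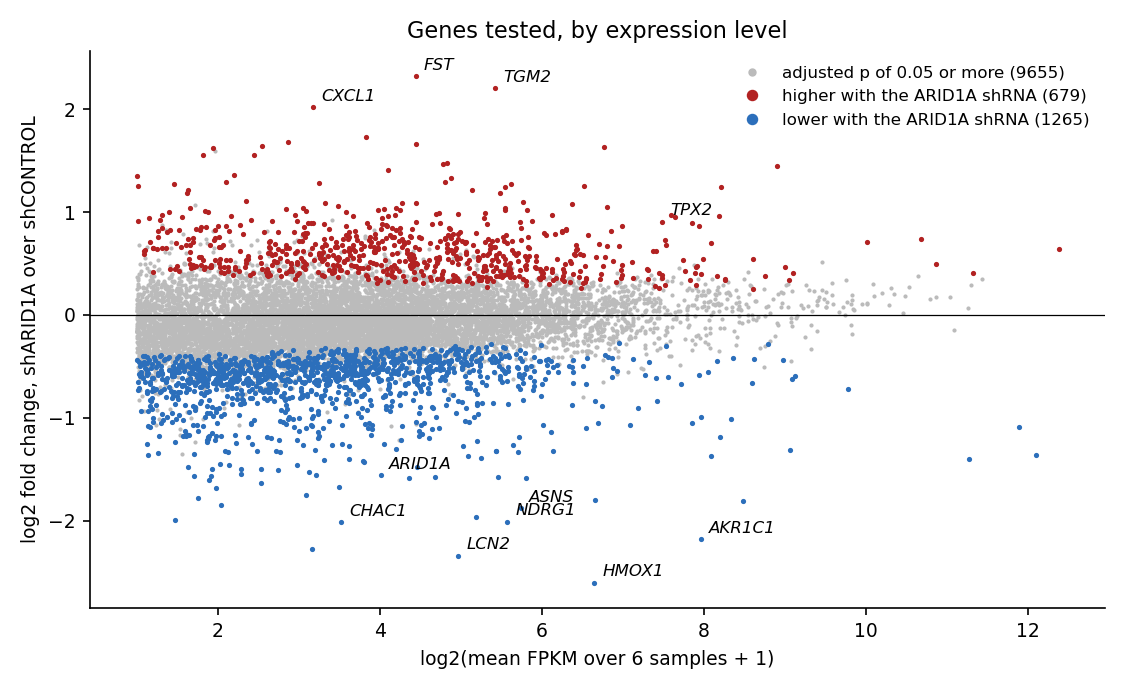
Log2 fold change, shARID1A over shCONTROL, on log2(FPKM + 1) values (vertical axis) against log2 of the mean FPKM over the 6 samples plus 1 (horizontal axis), 1 point per gene tested. Genes with an adjusted p below 0.05 are red where higher (679) and blue where lower (1265), and the other genes are grey.

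Cell cycle genes were higher with the ARID1A shRNA, in both phases for which a list had been fixed. Of 30 genes of G2/M and mitosis, 26 rose and 0 fell over all genes tested, and 29 rose when adjusted over the list alone. The median log2 fold change was 0.69. MKI67, the proliferation marker Ki-67, rose from 25.3 ± 1.51 to 51.3 ± 1.59 FPKM, the spindle assembly factor TPX2 from 124 ± 5.29 to 233 ± 9.65 FPKM, and the mitotic kinesin KIF20A from 40.0 ± 2.62 to 76.2 ± 7.55 FPKM. Of 34 E2F and G1/S genes, 23 rose and 0 fell, 29 rose when adjusted over the list alone, and the median was 0.50. CDC25A, the phosphatase that activates CDK2, rose from 6.96 ± 0.23 to 15.0 ± 0.56 FPKM, RRM2, a ribonucleotide reductase subunit, from 82.6 ± 3.79 to 146 ± 6.13 FPKM, and cyclin A2 (CCNA2) from 33.8 ± 1.51 to 58.6 ± 4.52 FPKM. These 6 genes had adjusted p-values from 0.000652 to 0.00212 and passed without each library in turn. Of the E2F list 14, 10 and 12 genes rose without shCONTROL replicate 1, shCONTROL replicate 2 and shARID1A replicate 1, and of the G2/M list at least 19 rose without any 1 library. By the camera test with a preset correlation the adjusted p was 6.5e-25 for the G2/M list and 7.6e-21 for the E2F list. With an estimated correlation it was 0.00955 for each, and these were the only 2 of the 18 lists tested that passed in that setting.

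Among genes linked to MYC, to stemness and to drug export, a smaller share passed than in the cell cycle lists. Of 30 MYC target and ribosome biogenesis genes, 5 rose (SRM, RRS1, LDHA, FBL and PA2G4) and 1 fell (TFRC, the transferrin receptor), against 7 and 1 when adjusted over the list alone. With the replicate block 10 rose and 1 fell. The median was 0.22. SRM, spermidine synthase, rose from 80.5 ± 4.02 to 120 ± 18.3 FPKM, and RRS1, a ribosome assembly factor, from 58.5 ± 3.32 to 78.7 ± 5.60 FPKM. The camera adjusted p was 1.7e-05, and the call was lost with an estimated correlation (adjusted p = 0.262 with an estimated correlation). SRM, RRS1, LDHA, FBL and PA2G4 each missed the threshold without shCONTROL replicate 1, 2 or 3 or shARID1A replicate 1, with adjusted p up to 0.0741, 0.0868, 0.118, 0.104 and 0.134. TFRC missed it without any library except shARID1A replicate 3 (up to 0.196) and in 5 other settings. Of the whole list 0 passed without shCONTROL replicate 1, 2 or 3 or shARID1A replicate 1, 8 rose without shARID1A replicate 2 and 12 rose without shARID1A replicate 3. Of 12 stem cell and cancer stemness markers tested (of 20 in the fixed list), 0 rose and 3 fell, the retinal dehydrogenase ALDH1A1 and the transcription factors KLF4 and SOX9. Adjusted over the list alone, and likewise with the replicate block, 1 rose and 3 fell. SOX9 fell from 36.2 ± 3.79 to 26.1 ± 3.27 FPKM, KLF4 from 10.9 ± 0.23 to 8.31 ± 0.18 FPKM, and ALDH1A1 from 2.37 ± 0.74 to 0.990 ± 0.20 FPKM. Without 4 of the 6 libraries in turn, each of these 3 calls ended, with adjusted p up to 0.120 for ALDH1A1 (shCONTROL 1 and 2, shARID1A 1 and 2), 0.146 for KLF4 (shCONTROL 1, 2 and 3, shARID1A 1) and 0.142 for SOX9 (the same 4 libraries as ALDH1A1). The list's median was 0.05 and its mean -0.01, opposite in sign, and camera gave an upward direction with an adjusted p of 0.720. Of 6 drug efflux transporters tested (of 10 in the fixed list), 0 passed over all genes tested and 2 fell when adjusted over the list alone (camera adjusted p = 0.464). The nearest to the threshold was ABCC5, at 48.2 ± 2.57 and 37.8 ± 4.24 FPKM, with an adjusted p of 0.0547, which was 0.0275 with the replicate block, where it was the 1 that fell, and ranged from 0.00825 to 0.188 over the alternatives.

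Epithelial and mesenchymal genes moved in several directions. Of 20 mesenchymal and EMT genes, 7 rose and 0 fell over all genes tested, 8 rose when adjusted over the list alone, 10 rose with the replicate block, and the median was 0.34. Only 4 rose without shCONTROL replicate 1, shCONTROL replicate 2 or shARID1A replicate 1. PLAU, the urokinase plasminogen activator, rose from 14.2 ± 2.32 to 41.0 ± 1.75 FPKM, fibronectin (FN1) from 10.98 ± 1.11 to 23.7 ± 2.12 FPKM, and vimentin (VIM) from 2.24 ± 0.43 to 5.95 ± 0.72 FPKM. The camera adjusted p was 2.1e-05, and the call was lost with an estimated correlation (adjusted p = 0.202 with an estimated correlation). Of 19 epithelial junction genes, 4 fell (DSP, F11R, JUP and CLDN7) and 1 rose (CLDN1), with the same counts when adjusted over the list alone (median -0.16, camera adjusted p = 0.294), and with the replicate block 5 fell and 2 rose. Desmoplakin (DSP) fell from 54.7 ± 1.97 to 34.5 ± 0.56 FPKM and plakoglobin (JUP) from 472 ± 40.9 to 301 ± 50.6 FPKM. The calls for CLDN7 and CLDN1 ended without shCONTROL replicate 1 or 2 or shARID1A replicate 1 (up to 0.112 and 0.119), and 7 fell and 2 rose without shARID1A replicate 3. Of 19 basal keratinocyte and hemidesmosome genes, 5 rose, among them COL17A1, ITGA3, ITGB4 and LAMA3, and 5 fell (KRT16, DSG3, KRT5, TP63 and PLEC), against 6 and 8 both when adjusted over the list alone and with the replicate block. Genes of the attachment to the basement membrane moved both ways, since PLEC, which encodes the hemidesmosome protein plectin, fell while COL17A1, ITGA3, ITGB4 and LAMA3 rose. KRT16 fell from 16.9 ± 4.99 to 5.70 ± 1.29 FPKM, with the reservation that KRT16 has close paralogs. The calls for ITGA3, ITGB4, LAMA3, TP63 and PLEC ended without shCONTROL replicate 1 or 2 or shARID1A replicate 1 (up to 0.117), that for COL17A1 without these or shARID1A replicate 2 (up to 0.103), and that for KRT5 without shCONTROL replicate 2 or shARID1A replicate 1 or 2 (up to 0.104). This list's median was -0.13 while camera gave an upward direction (adjusted p = 0.769).

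Of 10 keratinocyte terminal differentiation genes tested (of 32 in the fixed list), 3 fell (NOTCH3, KRT10 and CALML5) and 1 rose (IVL), against 6 and 1 when adjusted over the list alone and 5 and 1 with the replicate block, and the median was -0.47. KRT10, a keratin of suprabasal cells, fell from 26.1 ± 3.02 to 14.6 ± 4.10 FPKM and the receptor NOTCH3 from 12.3 ± 0.35 to 7.81 ± 0.88 FPKM. IVL, which encodes the cornified envelope protein involucrin, rose from 0.677 ± 0.11 to 1.63 ± 0.54 FPKM, a low level in both groups. The list had a camera adjusted p of 0.0861, which was 0.0487 with the replicate block and ranged from 0.00635 to 0.827 over the alternatives. The call for NOTCH3 ended without shCONTROL replicate 2 (adjusted p = 0.0559), that for KRT10 without shCONTROL replicate 1 or 2 (up to 0.0971), that for CALML5 without shCONTROL replicate 1 or 2 or shARID1A replicate 2 (up to 0.132), and that for IVL without any library except shARID1A replicate 3 (up to 0.121). Of the list 5 fell and 1 rose without shARID1A replicate 3.

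Part of the stress response genes were lower with the ARID1A shRNA. Of 23 unfolded protein and integrated stress response genes, 11 fell and 0 rose over all genes tested, and 14 fell and 3 rose when adjusted over the list alone. With the replicate block 14 fell and 3 rose over all genes. The 3 were in both cases the endoplasmic reticulum chaperone HSPA5 and the protein disulfide isomerases PDIA4 and PDIA6, with log2 fold changes of 0.48, 0.40 and 0.32 (adjusted p over all genes without the block 0.0988, 0.0789 and 0.0875). The median of the list was -0.45. ASNS, asparagine synthetase, fell from 83.1 ± 6.80 to 21.9 ± 0.94 FPKM, DDIT4, an inhibitor of mTORC1, from 65.0 ± 7.38 to 21.0 ± 1.02 FPKM, and the transcription factor ATF3 from 12.2 ± 0.83 to 2.94 ± 0.61 FPKM (limma, adjusted p from 0.000116 to 0.000323). The camera adjusted p was 0.000352, and the call was lost with an estimated correlation (adjusted p = 0.262 with an estimated correlation). Among 20 p53 target genes, 7 fell and 1 rose (PLK3), against 8 and 2 when adjusted over the list alone (median -0.14, camera adjusted p = 0.140). The call for PLK3 ended without any library except shARID1A replicate 3 (up to 0.161) and in 2 other settings. Of this list 4 fell without shCONTROL replicate 1, shCONTROL replicate 2 or shARID1A replicate 1, and 7 fell and 3 rose without shARID1A replicate 3. CDKN1A, which encodes the cell cycle inhibitor p21, fell from 73.8 ± 9.94 to 28.7 ± 1.90 FPKM, GADD45A, a stress-induced growth arrest gene, from 79.1 ± 3.55 to 51.0 ± 5.36 FPKM, and BBC3, which encodes the pro-apoptotic protein PUMA, from 2.67 ± 0.55 to 0.776 ± 0.078 FPKM.

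Of 20 hypoxia and glycolysis genes, 6 fell and 3 rose (PGAM1, ADM and LOXL2), against 6 and 4 when adjusted over the list alone (median -0.08, camera adjusted p = 0.720). The calls for PGAM1 and LOXL2 ended without shCONTROL replicate 1, 2 or 3 or shARID1A replicate 1 (up to 0.101 and 0.0886), and that for ADM without any library except shARID1A replicate 3 (up to 0.132). In this list 3, 2 and 2 members fell without shCONTROL replicate 1, shCONTROL replicate 2 and shARID1A replicate 1. NDRG1 fell from 75.2 ± 7.98 to 17.9 ± 1.92 FPKM, and the angiogenic factor VEGFA from 40.2 ± 4.48 to 25.2 ± 0.53 FPKM. EGLN3, a prolyl hydroxylase, stood at 3.79 ± 0.77 and 2.03 ± 0.20 FPKM (adjusted p = 0.0181), and its call ended without shCONTROL replicate 2 or shARID1A replicate 1 (up to 0.0696). Of 24 cholesterol synthesis genes, 6 fell and 0 rose, with the same counts when adjusted over the list alone and a median of -0.29. Of these genes 2, 2 and 3 fell without shCONTROL replicate 1, shCONTROL replicate 2 and shARID1A replicate 1, and 10 fell and 2 rose without shARID1A replicate 3. MSMO1, a sterol methyl oxidase, fell from 28.4 ± 1.07 to 14.8 ± 2.16 FPKM and the sterol reductase TM7SF2 from 4.46 ± 0.48 to 1.42 ± 0.33 FPKM. HMGCS1, the HMG-CoA synthase, stood at 23.5 ± 3.58 and 14.4 ± 1.77 FPKM (adjusted p = 0.0153), and its call ended without shCONTROL replicate 1 or 2 (up to 0.0787). The list had a camera adjusted p of 0.0522, which was 0.0402 with the replicate block and ranged from 0.0126 to 0.497 over the alternatives.

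Signalling genes included cytokines that rose and interferon-stimulated genes that fell. Of 15 NF-kB and inflammatory cytokine genes tested (of 26 in the fixed list), 6 rose and 1 fell (LCN2), with the same counts when adjusted over the list alone. With the replicate block 8 rose and 1 fell. The median was 0.65. The 6 that rose were CXCL1, CXCL2, CXCL3, CXCL8, IL1B and PTGS2. CXCL1 rose from 2.58 ± 0.69 to 13.4 ± 1.61 FPKM and CXCL8, interleukin 8, from 1.75 ± 0.23 to 7.17 ± 1.48 FPKM, and CXCL1, CXCL2 and CXCL3 resemble one another in sequence, so that reads may be shared among them. The calls for CXCL2 and CXCL3 ended without shCONTROL replicate 1 or shARID1A replicate 1 (up to 0.0560 and 0.0712), that for PTGS2 without shCONTROL replicate 1 or 2 or shARID1A replicate 1 (up to 0.108), and that for IL1B without these or shARID1A replicate 2 (up to 0.0855), so that 2 rose without shCONTROL replicate 1 or shARID1A replicate 1. The camera adjusted p was 0.000727, and the call was lost with an estimated correlation (adjusted p = 0.104 with an estimated correlation) and with genes of at least 5 FPKM only (0.293). Of 19 interferon response genes, 4 fell (ISG15, IFI6, IRF7 and STAT2) and 0 rose, and 7 fell when adjusted over the list alone, also with the replicate block. The median was -0.32. ISG15, a ubiquitin-like interferon-induced protein, fell from 25.2 ± 5.08 to 9.51 ± 0.64 FPKM. The camera adjusted p was 0.0231. That call was lost with an estimated correlation (adjusted p = 0.262 with an estimated correlation), without a filter (0.177), with genes of at least 5 FPKM only (0.174) and without shARID1A replicate 2 (0.0559). The calls for IFI6 and IRF7 ended without shCONTROL replicate 1 or 2 or shARID1A replicate 1, with adjusted p up to 0.0934 and 0.126, and that for STAT2 without any library except shARID1A replicate 3 (up to 0.113). In all, 6 fell and 1 rose without shCONTROL replicate 3, and 7 fell without shARID1A replicate 3.

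Of 24 EGFR and MAPK output genes, 8 rose and 5 fell (ERRFI1, SPRED1, SPRED2, ETV5 and EGR1), against 11 and 6 when adjusted over the list alone, with a median of 0.18. EPHA2, a receptor tyrosine kinase, rose from 53.9 ± 1.58 to 96.0 ± 5.35 FPKM and the MAP kinase phosphatase DUSP4 from 4.52 ± 0.58 to 9.32 ± 0.17 FPKM. ERRFI1, which encodes an inhibitor of EGFR, fell from 35.5 ± 2.72 to 19.9 ± 2.92 FPKM. Known inhibitors of this pathway were found on both sides, SPRY1, DUSP4 and DUSP5 among the genes that rose (log2 fold changes 0.81, 0.91 and 0.72) and ERRFI1, SPRED1 and SPRED2 among those that fell. The call for SPRED1 (adjusted p = 0.0496) ended without any library except shARID1A replicate 3 (up to 0.181) and in 7 other settings. That for SPRED2 ended without shCONTROL replicate 1 or 2 or shARID1A replicate 1 (up to 0.129), that for ETV5 without these or shARID1A replicate 2 (up to 0.158), and that for DUSP5 without shCONTROL replicate 2 or 3 or shARID1A replicate 1 or 2 (up to 0.116). In all, 5, 4 and 4 rose and 2 fell without shCONTROL replicate 1, shCONTROL replicate 2 and shARID1A replicate 1, and 9 rose and 3 fell without shARID1A replicate 2. The camera adjusted p was 0.0367. That call was lost with an estimated correlation (adjusted p = 0.202 with an estimated correlation), with genes of at least 5 FPKM only (0.174), after quantile normalization (0.0687), after length and GC correction with the replicate block (0.0527) and without shARID1A replicate 2 (0.0702).

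Among 24 other SWI/SNF subunit genes, 20 did not pass, 3 fell (SMARCC1, SMARCD3 and GLTSCR1L, now named BICRAL) and 1 rose (DPF1), with the same counts when adjusted over the list alone. Of all genes tested 16.8% passed, a share near that of this list. SMARCC1, the scaffold subunit BAF155, fell from 47.6 ± 1.83 to 30.9 ± 0.42 FPKM (log2 fold change -0.61, limma adjusted p = 0.00307) and passed in every alternative. GLTSCR1L stood at 5.63 ± 0.33 and 3.77 ± 0.27 FPKM and DPF1 at 2.63 ± 0.072 and 3.84 ± 0.35 FPKM. The call for SMARCD3 (adjusted p = 0.0477) ended without any library except shARID1A replicate 3 (up to 0.180) and in 6 other settings. That for GLTSCR1L ended without shCONTROL replicate 1, 2 or 3 or shARID1A replicate 1 (up to 0.104) and that for DPF1 without any library except shARID1A replicate 3 (up to 0.138), the library without which 4 fell and 3 rose. The list's median was -0.06, above the median of all genes tested (-0.08). Camera, which compares a list with the other genes, gave an upward direction (adjusted p = 0.940).

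Markers of other cell types were near 0 or similar in the 2 groups, with 1 exception. Of 10 fibroblast markers, 2 had a mean of at least 1 FPKM. LUM, the proteoglycan lumican, rose from 4.64 ± 1.16 to 8.77 ± 1.30 FPKM (limma, adjusted p = 0.0156), a call that ended without shCONTROL replicate 1 or 2 or shARID1A replicate 1 (up to 0.0754). COL1A1 stood at 2.78 ± 0.37 and 2.43 ± 0.24 FPKM (adjusted p = 0.463), while COL1A2 and COL3A1, which fibroblasts express abundantly, were below 0.05 FPKM on average in each group. Of the leukocyte markers only CD68 was tested, at 13.6 ± 2.04 and 12.4 ± 3.09 FPKM (adjusted p = 0.630), and PTPRC was below 0.05 FPKM. Transcripts of replication-dependent histone genes mostly, though not always, lack a poly(A) tail. Of 9 such genes tested, 1 rose (HIST1H2BJ) and 1 fell (HIST1H2BD), 1 and 3 with the replicate block. The histone list had a camera adjusted p of 0.490. The call for HIST1H2BJ ended without shCONTROL replicate 1 or 2 or shARID1A replicate 1 or 2 (up to 0.0770). LUM, HIST1H2BJ and HIST1H2BD, and members named above other than the 3 with the smallest p in each list, were named after their values were seen.

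**Figure D3:**
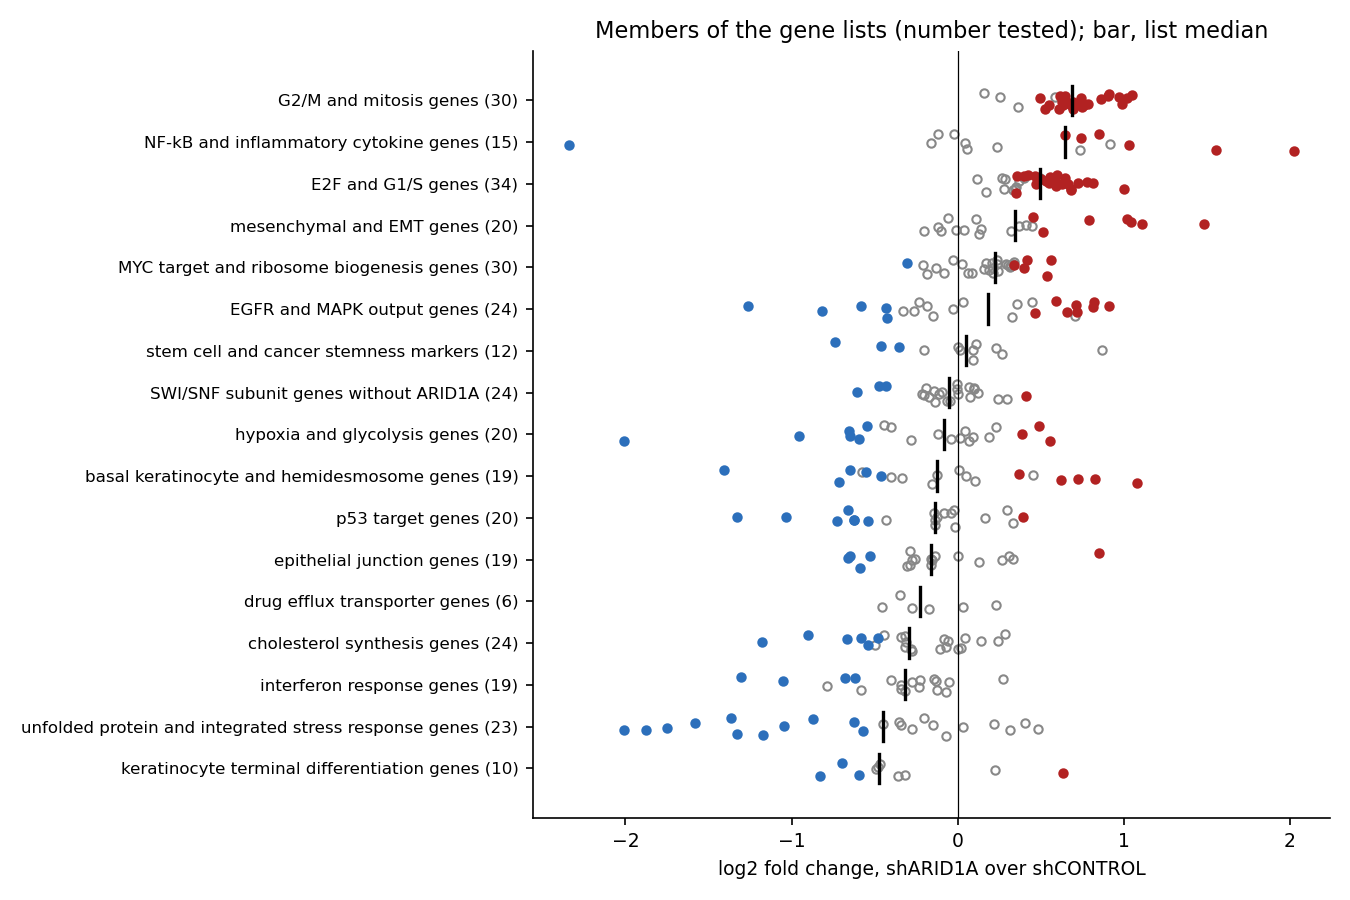
Log2 fold change, shARID1A over shCONTROL, on log2(FPKM + 1) values (horizontal axis) of each tested member of the gene lists (1 row per list, number tested in brackets); red and blue points passed an adjusted p of 0.05 over all genes tested and were higher or lower, open points did not pass, and black bars are list medians. The medians range from -0.47 for keratinocyte terminal differentiation genes to 0.69 for G2/M and mitosis genes, and points are shifted vertically at random for display.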

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

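The corrected fits, the tests of a single scaling factor and of a uniform background, and all work on the rows with another denominator, were chosen only after the results were seen.

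The 393 rows at the end of the table, which take no part in the report's comparison, stood out because they carry a difference between the groups of their own. Of 213 genes with at least 1 FPKM in both listings, 33.3% had shARID1A and shCONTROL values that did not overlap in these rows, against 32.4% for the same genes in the main rows and 10% by chance. The log2 fold changes of the 2 listings correlated across genes with Pearson's r of 0.377 and Spearman's rho of 0.249, and genes are not independent replicates. The recovered reads of equally named columns differed by a chi-square of 26.4 to 117 per degree of freedom, far more than counting noise.

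Cell cycle genes were higher with the ARID1A shRNA (median log2 fold change of the G2/M and E2F lists together 0.604). The tables argue against a trend with transcript length, GC content or expression level, since the lower of the medians in the corrected fits with the replicate block was 0.604 and both lists passed in both fits. They argue against a single library too, since the median nearest 0 without a library was 0.574. A different growth phase or density of the cultures at harvest, an effect of the shRNA on genes other than ARID1A, and a consequence of less ARID1A were not tested and stay open, because each goes with the groups. Cultures matched in density, another shRNA against ARID1A or its re-expression would be needed to separate them.

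Of 23 unfolded protein and integrated stress response genes 11 were lower (median of the list -0.452), while HSPA5, PDIA4 and PDIA6 had log2 fold changes above 0 that passed over the list alone and with the replicate block. After correction in the fits with the replicate block the median nearest 0 was -0.462 and the list passed in both fits, and without a library the median nearest 0 was -0.421, so neither a trend with length, GC content or level nor a single library accounts for it. With an estimated correlation the list did not pass (adjusted p = 0.262), and the estimated correlation of its members was 0.176. Nutrient supply and culture density, which regulate these genes, could differ between the groups and were not tested, and no biological explanation beyond the shRNA groups was tested.

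More genes were lower than higher, and the median change fell at low expression. With a pseudocount of 0.1 FPKM the median log2 fold change was -0.25 in the lowest eighth of genes by mean expression and 0.04 in the highest, a difference of 0.294, which 1 scaling factor per sample cannot give. A uniform background of reads in the shCONTROL samples is also argued against, since protein-coding genes not tested had a median of 0.0654 FPKM there, while the lowest eighth lost a median of 0.266 FPKM. A background that is not uniform cannot be told apart: the share of reads on 86 receptor and hair keratin-associated genes had a ratio of shARID1A to shCONTROL of 1.22. A ratio of at least 0.95 had been set to speak against background, but 1 gene decided the value, and the ratio without it was 0.913. A difference in RNA content per cell, which FPKM removes, was not tested and may also play a part.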

How the results depend on the processing

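The voom, cyclic loess, and length and GC alternatives were chosen after seeing the data. ARID1A kept its direction and its call in every alternative, with log2 fold changes from -1.68 (voom) to -1.20 (pseudocount of 5 FPKM), and so did the E2F and G2/M lists, with adjusted p of at most 0.00955. Of 58 named genes past the threshold, 43 passed without each library in turn. The other 15 lost their calls without at least 1, and 11 of these (LDHA, ALDH1A1, KLF4, SOX9, KRT10, IVL, GLTSCR1L, DPF1, IFI6, IRF7 and EGLN3) in another setting too. Of the 99 other members of the fixed lists past the threshold, 66 lost their calls without at least 1 library. For the 64 named genes other than ARID1A, the settings that keep all libraries gave 793 values on the same side of the threshold, 16 weaker, 9 stronger and 2 with the sign turned, both for ARID1B (0.047 after quantile normalization and 0.0558 after cyclic loess with the replicate block). Leaving out a library gave 327, 51, 3 and 3, the last for RB1 (-0.347 to 0.0815) and MYC (-0.340 to 0.0528). The cause was not tested except where stated. The count of changed genes was 4288 after length and GC correction with the replicate block (1474 higher, 2814 lower), and without a library it ranged from 587 (shCONTROL 2) to 3403 (shARID1A 3), with 231 to 1116 higher and 356 to 2287 lower. With 1 sample fewer the fit has fewer degrees of freedom, and shARID1A 3 is the sample apart on the second component. Cyclic loess with the block gave 1251 higher, quantile normalization 831 lower, and a minimum of 5 FPKM, which tests fewer genes, 820 lower. Changes of at least 2-fold numbered 363 with a pseudocount of 0.1 and 68 with 5 FPKM, since a pseudocount shrinks folds, 136 with a minimum of 5 FPKM and 392 with voom. For the lists, an estimated correlation ended the calls for MYC targets (0.262), mesenchymal genes (0.202), EGFR output (0.202), interferon (0.262), NF-kB (0.104) and the stress response (0.262). This setting changes both the correlation and the degrees of freedom. For EGFR output and NF-kB the estimated correlation, -0.016 and -0.057, was below the preset 0.01. This argues against correlated members as the reason for those losses. For MYC targets (0.169), mesenchymal (0.118), interferon (0.0508) and stress response genes (0.176) the estimated correlation was above the preset. There, correlation and degrees of freedom were not separated. A minimum of 5 FPKM ended the calls for EGFR output (0.174), interferon (0.174) and NF-kB (0.293), gave 0.00635 for keratinocyte differentiation, and turned the sign for stemness (0.817) and SWI/SNF (0.936). No filter gave 0.177 for interferon and 0.0326 for cholesterol. Quantile normalization gave 0.0687 for EGFR output and 0.0149 for cholesterol, and turned the sign for basal (0.454) and SWI/SNF genes (0.827). Cyclic loess with the replicate block gave 0.0494 for keratinocyte differentiation and 0.0126 for cholesterol, both also past the threshold with the block alone, and turned the sign for basal (0.535) and SWI/SNF genes (0.814). Upper quartile scaling gave 0.049 for cholesterol, and length and GC correction with the block 0.0314 for cholesterol, which the block alone also passed, and 0.0527 for EGFR output, against 0.0278 with the block alone. The replicate block gave 0.0487 for keratinocyte differentiation, 0.0402 for cholesterol, 0.0264 for E2F1 and 0.0275 for ABCC5, and changed no other call of a list or named gene, with 2740 genes changed. Fry, which does not compare a list with other genes, passed keratinocyte differentiation (0.0114), junction (0.0056), p53 (0.00129), hypoxia (0.0163), cholesterol (0.0227) and efflux genes (0.0114), and was opposite in direction for stemness (0.361), basal (0.557) and SWI/SNF genes (0.0227). Without a library the adjusted p ranged from 0.0272 (shCONTROL 2) to 0.155 for keratinocyte differentiation, 0.35 to 0.96 for basal, 0.857 to 0.953 for SWI/SNF, 0.0229 to 0.0702 (shARID1A 2) for EGFR output, 0.00461 to 0.0559 (shARID1A 2) for interferon and 0.014 (shCONTROL 3) to 0.329 for cholesterol. Counting noise alone does not account for the spread within groups, whose samples differed by a chi-square of 5.56 to 90.5 per degree of freedom. This value is pooled over genes and says little of genes with few reads. Among called genes, IFI6 and IVL had 39 and 43 reads in their lowest sample, where counting noise may matter.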

Other observations

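The lists in this part were written after the largest changes had been seen, and the tests of the lists were run on the members whose values had not been seen, those with an estimated correlation only after the other results were seen.

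Genes of the oxidative stress regulator NRF2 were lower with the ARID1A shRNA. Of 24 tested, 21 fell and 0 rose over all genes tested, with a median log2 fold change of -1.06. FTH1 and FTL, the ferritin chains, fell from 6295 ± 87.7 to 2450 ± 219 FPKM and from 5169 ± 338 to 2434 ± 89.8 FPKM, with pseudogenes that may share their reads. NQO1, a quinone reductase, fell from 432 ± 14.4 to 215 ± 15.7 FPKM (limma, adjusted p = 0.000591). The 18 members not seen before gave a camera adjusted p of 1.5e-11 over these lists, and an adjusted p of 0.00670 with an estimated correlation. Of 20 autophagy and lysosome genes, 13 fell and 0 rose (median -0.70), among them the autophagy receptor SQSTM1, from 762 ± 120 to 305 ± 31.3 FPKM, and the kinase ULK1, from 19.4 ± 3.41 to 6.55 ± 0.73 FPKM. The 18 members not seen before gave 2.1e-06, and an adjusted p of 0.0123 with an estimated correlation. Of the members named for lysosomes or transport to them, LAMP1 fell (adjusted p = 0.0215, up to 0.0940 without shCONTROL replicate 1, 2 or 3), while CTSD, MCOLN1 and VPS18 did not pass (0.239, 0.471 and 0.484). That NRF2 target genes and autophagy genes are lower as groups may be a hypothesis, found and tested on the same samples. The lists share members with lists fixed before the data were examined, 3 for NRF2, 1 for autophagy, 2 for YAP and TAZ, 1 for actin and 0 for metallothioneins.

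Of 21 actin cytoskeleton genes, 8 rose and 0 fell (median 0.30), among them ACTB, from 4121 ± 365 to 6523 ± 1360 FPKM, a call that ended without shCONTROL replicate 1 or 2 or shARID1A replicate 1 (adjusted p up to 0.108). Without each of these 3 libraries 1 actin gene rose (TAGLN), 5 rose without shARID1A replicate 2 and 14 without shARID1A replicate 3. The 19 members not seen before gave a camera adjusted p of 8.4e-05, and an adjusted p of 0.269 with an estimated correlation. Of 21 YAP and TAZ target genes, 4 rose and 2 fell (median 0.37), and 1 fell without shCONTROL replicate 1, 2 or 3 or shARID1A replicate 1. The 18 members not seen before gave 0.000196, and an adjusted p of 0.0260 with an estimated correlation, although the whole list, seen members included, gave 0.0801. Both may be higher as groups, as hypotheses, and the estimated correlation ended the call for the actin list. The metallothionein list had 5 tested members, 1 of which, SLC30A1, encodes a zinc transporter and not a metallothionein. Of the 5 members 1 rose, MT2A, from 257 ± 3.08 to 701 ± 39.8 FPKM. The 4 others, SLC30A1 (0.316) included, had a median log2 fold change of 0.292, and 1 of them rose without shARID1A replicate 3. They were too few for the test, so whether the family rose is not settled.

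The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1944 genes changed, 209 at least 2-fold, 679 higher and 1265 lower, the highest of 10, and the highest of the others was 0 in each case (limma, and voom on the recovered reads), with 37 to 691 genes at an unadjusted p under 0.05 against 3929 in the real split. Among the splits that part all 3 replicate pairs, the others gave 0 with the replicate block and the real one 2740. For gene lists by camera with the preset correlation, the real split gave 8 past the threshold and so did the highest of the others, so that 2 of the 10 splits gave as many, and the fewest was 3. The E2F and G2/M lists passed in all 9 others, with adjusted p no smaller than 1.8e-07 and 3.0e-10 against 7.6e-21 and 6.5e-25 in the real split. For 2 other lists past the threshold another split gave a smaller adjusted p than the real one, 1.6e-06 against 2.1e-05 for mesenchymal and 0.0147 against 0.0231 for interferon genes. The MYC, NF-kB and stress response lists passed in 5, 3 and 2 of the other splits and the EGFR list in 0, none of them with a smaller p than in the real split. Each other split sets 2 samples of a group against the remaining 1, so it keeps part of the group difference. The rest of that difference widens the spread within its sides. Counts of 0 genes in the other splits, with or without the replicate block, were therefore likely from the start and do not measure chance.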
